A study of Homo sapiens with 4 samples.

How the data were processed

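The series holds 4 RNA sequencing libraries, 1 each from Hep3B, HepG2, Huh-7D12 and SK-Hep-1, which are lines of liver cancer. Per the labels, total RNA was treated with DNase, depleted of ribosomal RNA and made into stranded libraries without the poly(A) selection step, and sequenced as 100-bp paired ends on a HiSeq 2500. Such libraries retain circRNAs and replication-dependent histone messages, which have no poly(A) tail. The submitters' processing notes name STAR 2.6.1d and the hg38 genome build, without their role. The circRNA caller, the read counter, the annotation release and the method of normalization are not given in the sources used here.

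The deposited signal values are normalized read numbers: the authors multiplied the whole reads of each library by 1 factor, the same factor in the gene table and in the circRNA table. This was tested on the files. Dividing each value by the smallest value above 0 of its library gave whole numbers for 100% of the values in both tables, within a tolerance of 0.001. The factors were 0.890 in Hep3B, 1.39 in HepG2, 1.08 in Huh-7D12 and 1.35 in SK-Hep-1, and all read numbers in the text are the whole numbers so recovered. The circRNA table gives back-splice reads per circRNA. An empty value there was taken as 0 reads. Of its 12473 circRNAs, 4473 had no value in any of the 4 lines and were left out.

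Gene reads summed to 24409250 in Hep3B, 22950383 in HepG2, 18581156 in Huh-7D12 and 20938569 in SK-Hep-1, of which 17283875, 12075008, 15340422 and 13644009 lay outside mitochondrial genes. A gene had at least 1 read in 22383, 20872, 22830 and 20196 cases. Exact 95% Poisson intervals were given for levels, and Wilson intervals for most shares. Exact binomial (Clopper-Pearson) intervals were given for ratios of 2 libraries and for shares of circRNAs whose host gene stood higher. Against a library with 0 reads a fold was computed to a floor of 3 reads per library, which is 0.105, 0.164, 0.127 and 0.158 on the per-million scale in the order above, and is written "at least". Where all 3 other lines had 0 reads, the floor of the one with the largest factor was taken. For circRNAs such bounds can lie under 4-fold for circRNAs that pass 4-fold on the scale with pseudocount.

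For genes, deposited values were scaled so that the mean column total equals that of a per-million scale, and log2 levels were taken after adding a pseudocount of 1. Genes entered when the highest of the 4 levels was at least 1, which held for 15850 of 29670. Symbols, gene types and positions were taken from GENCODE 29 through the Ensembl identifiers, all of which matched (29670); 12 names had been turned into dates in the table. For circRNAs the pseudocount was the median over lines of the smallest value above 0 (1.21), and a circRNA entered when its highest level was at least 5 times that (6.07). The deposited circRNA positions are the bases that flank the loop; positions are printed as the first and last base inside it, counted from 1 on GRCh38. Exon numbers refer to the transcript that matched both ends. The 282 circRNAs with 2 or more host genes and the 114 with none assigned in the deposited table were left out of comparisons with host genes.

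Lines were compared by size only, since 1 library per line leaves no residual degrees of freedom for a model. The 4-fold rule, the entry levels, 26 gene lists, a list of 66 circRNA host genes and the alternatives, apart from those named below as added, were fixed before the data were examined. A gene list was described by the median over its measured members of the log2 difference between a line and the mean of the other 3, and by the percentile of that median among 10000 random lists of the same size matched in 20 bins of mean level; it was taken to lie outside them under 2.5 or above 97.5. Measured members are those that passed the entry level in at least 1 line. Because the other 3 lines include SK-Hep-1 for every other line, the medians of Hep3B, HepG2 and Huh-7D12 rise where SK-Hep-1 lacks a gene. The comparison without SK-Hep-1 was therefore added after seeing the data. Members shared between lists count in each; the EPCAM and CLDN4 genes, for example, are in the epithelial and cholangiocyte lists, and AXL is in the mesenchymal and TGF-beta lists. RGS5 is counted on both of its identifiers in the stellate list.

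The genes named in the text are, per line, the 8 with the largest distance above and the 4 with the largest distance below the other 3 lines, and up to 4 members of each list. XIST, Y-linked genes, pseudogenes and genes without a symbol were left out of that choice. The named circRNAs are the 10 with the highest mean, the 5 per line with the largest distance, the most abundant one of hosts in the fixed list, and the 5 host genes per line with the largest difference between circular and gene reads. Some genes and circRNAs chosen by these rules are not described. PECAM1 and the genes of neighbouring segments in the closing section were chosen after their values were seen. For host genes, back-splice reads were summed and set against gene reads of the same identifier, by Spearman correlation across genes and by a log2 difference of at least 2 between both.

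Alternatives were other pseudocounts (0.25 and 4 for genes, 0.25 and 4 times the main one for circRNAs), other entry levels (none and 5 for genes, none and 10 pseudocounts for circRNAs), TMM and median-of-ratios scaling, equal circRNA totals, higher detection limits and the most abundant circRNA of a host alone. Added after seeing the data were Poisson intervals that do not overlap, circRNAs with both ends at exon ends and 1 host, back-splice reads thinned by the ratio that makes reads outside mitochondrial genes equal, and SK-Hep-1 left out for genes and for lists. Median-of-ratios factors differed from the deposited scaling by 0.03 log2 or less. The rule was tested on simulated data: planted 8-fold differences were called for 100% of genes and 90% of circRNAs and 2-fold ones for 0%, and 0 of 14288 unchanged genes and 6 of 327 unchanged circRNAs were called. Differences were planted only in genes and circRNAs whose mean over the 4 lines already met the entry level. The 90% therefore does not apply to circRNAs with few reads in 1 line and none in the others. Computations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.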

Results

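Total RNA from the established human lines Hep3B, HepG2, Huh-7D12 and SK-Hep-1, all 4 of liver cancer, was depleted of ribosomal RNA and sequenced without poly(A) selection, so that reads came from linear and from circular RNA. The series concerns antisense oligonucleotides with locked nucleic acid that lower the level of circular RNAs (circRNAs), closed loops made when a downstream splice donor joins an upstream splice acceptor. The libraries described here give the circRNA and gene levels of the 4 lines, with 1 library per line and no replicates, so that no tests, p-values or standard deviations could be given. The gene table held 24409250 reads in Hep3B, 22950383 in HepG2, 18581156 in Huh-7D12 and 20938569 in SK-Hep-1. The circRNA table held 12916, 6235, 13515 and 7740 reads across back-splice junctions in the same order. A gene or circRNA is said to stand higher or lower in a line when its log2 level lay at least 2 (4-fold) above the highest or below the lowest of the other 3 lines. Folds are given to the nearest of those 3 lines, and the 95% intervals beside them and beside the levels cover counting error only. Gene levels are on a per-million scale and circRNA levels are in normalized back-splice reads.

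The first comparison asked how far the 4 lines differed in their gene levels. SK-Hep-1 stood apart from the other 3 lines: the genes of plasma proteins, of hepatic transcription factors and of liver metabolism were low or without reads, and genes of mesenchymal cells and of extracellular matrix were high. Hep3B, HepG2 and Huh-7D12 all expressed the hepatocyte genes. HepG2 differed from the rest by target genes of Wnt signalling and NRF2, Hep3B by the imprinted RNA H19 and by epithelial genes, and Huh-7D12 by SPINK1 and by BRDT, a gene of male germ cells. In SK-Hep-1 851 genes stood higher and 525 lower. The corresponding numbers were 232 and 183 in HepG2, 241 and 85 in Huh-7D12, and 128 and 71 in Hep3B, out of 15850 genes that entered. Across these genes, which are not independent replicates, the Spearman correlation was 0.852 between Hep3B and HepG2, 0.867 between Hep3B and Huh-7D12, and 0.820 between HepG2 and Huh-7D12. SK-Hep-1 had 0.685 with Hep3B, 0.688 with HepG2 and 0.698 with Huh-7D12. The numbers of genes depended on the pseudocount: with 4 in place of 1 they were 498 and 255 in SK-Hep-1, 135 and 63 in HepG2, 91 and 26 in Huh-7D12, and 48 and 18 in Hep3B. ROBO4, EGFL7, ECM1, BAMBI, TIMD4, SFN, HOXB13, HOXB3, ESRP2 and RBM20, named further on, did not pass 4-fold with it.

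**Figure D1:**
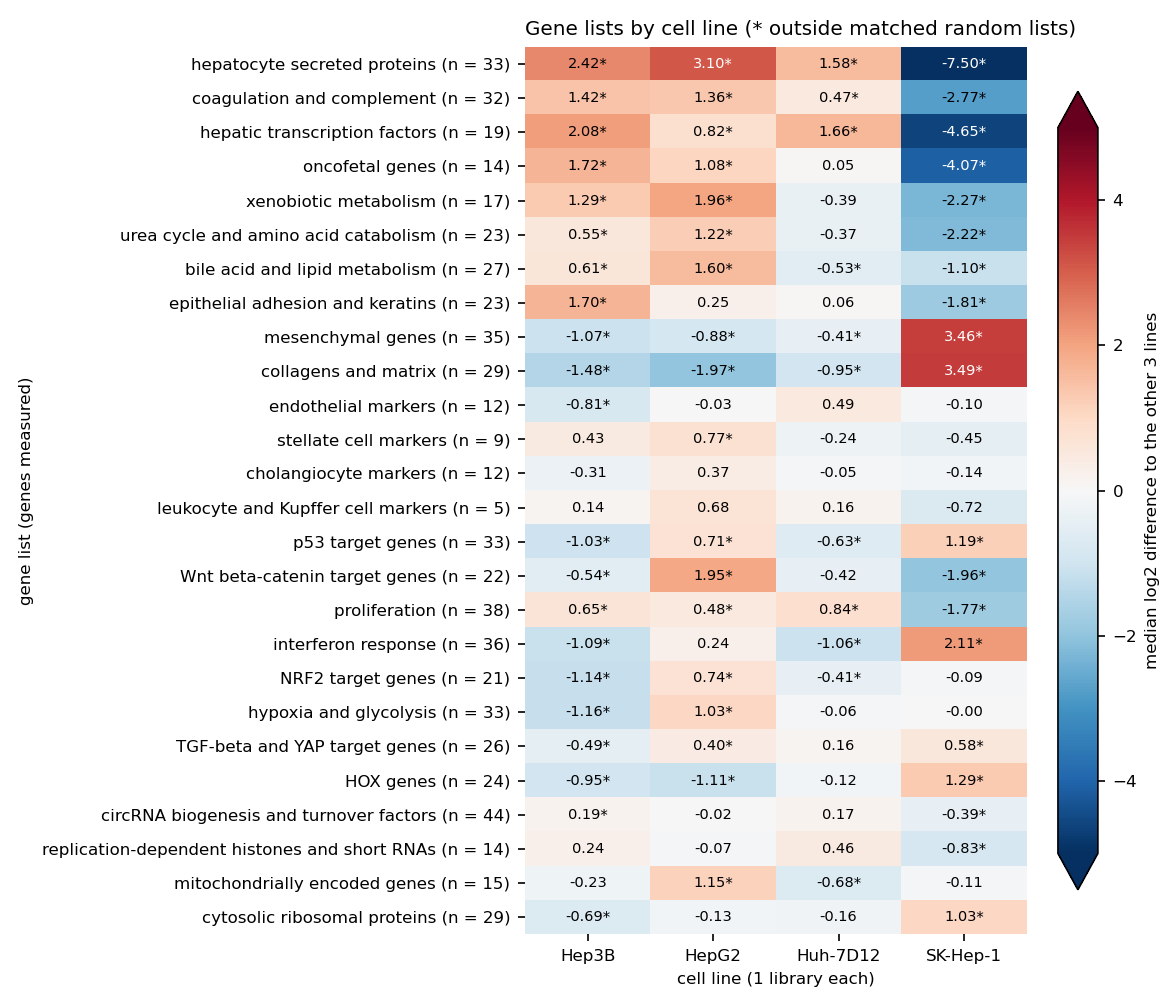
Median log2 difference between each cell line (columns, 1 library each) and the mean of the other 3 lines, for 26 gene lists (the number of measured genes is in parentheses). An asterisk marks medians outside the central 95% of matched random lists; the hepatocyte secreted proteins were at -7.50 in SK-Hep-1 and the collagens and matrix genes at 3.49.

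Many hepatocyte genes were low or without reads in SK-Hep-1. ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412), which encodes serum albumin, had 0 reads there against a level of 10412 in Hep3B, 4910.0 in HepG2 and 3011 in Huh-7D12, and was at least 19024-fold lower. APOB and APOA2, which encode apolipoproteins, had 2 and 5 reads in SK-Hep-1 and were 37731-fold (10445 to 311564) and 14902-fold (6385 to 45897) lower. TF, the gene of transferrin, was 11018-fold (1977 to 435224) lower. Over 33 measured genes of hepatocyte secreted proteins, 25 stood lower in SK-Hep-1, and the median differences were 2.42 in Hep3B, 3.10 in HepG2, 1.58 in Huh-7D12 and -7.50 in SK-Hep-1. Among 32 coagulation and complement genes, 13 stood lower in SK-Hep-1, with medians of 1.42 in Hep3B, 1.36 in HepG2, 0.47 in Huh-7D12 and -2.77 in SK-Hep-1. F2, which encodes prothrombin, SERPINF2 and F5 had 0 reads in SK-Hep-1 and were at least 562-fold, at least 796-fold and at least 719-fold lower, while C5 was 37.4-fold (29.6 to 48.0) lower. The transcription factors of hepatocytes went the same way: 13 of 19 stood lower in SK-Hep-1, and the medians were 2.08 in Hep3B, 0.82 in HepG2, 1.66 in Huh-7D12 and -4.65 in SK-Hep-1. HNF4A and the bile acid receptor gene NR1H4 had 0 reads in SK-Hep-1 and were at least 792-fold and at least 308-fold lower, and PROX1 was 2025-fold (363 to 80004) lower. These lists lay outside the matched random lists in all 4 lines. Part of the positive medians came from SK-Hep-1 being among the lines compared: without it, the median of the secreted proteins in Huh-7D12 was -0.62, that of coagulation and complement -1.11, and that of the transcription factors in HepG2 -0.39. Without it, the medians of the secreted proteins in Hep3B (0.05), of coagulation in Hep3B (0.08) and HepG2 (0.21) and of the transcription factors in Huh-7D12 (0.09) lay within the matched lists, as did that of coagulation in Huh-7D12 with a pseudocount of 4 (0.02) or no entry level (0.25).

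Judged by list medians, metabolic genes of the liver were low in SK-Hep-1 and highest in HepG2. Fewer members passed 4-fold. Of 17 genes of xenobiotic metabolism 5 stood lower in SK-Hep-1 and 2 higher in HepG2. For 23 genes of the urea cycle and amino acid catabolism these were 6 and 2, and 1 stood higher in SK-Hep-1. For 27 genes of bile acid and lipid metabolism they were 5 and 6. The medians were 1.29 in Hep3B, 1.96 in HepG2, -0.39 in Huh-7D12 and -2.27 in SK-Hep-1 for 17 genes of xenobiotic metabolism, 0.55 in Hep3B, 1.22 in HepG2, -0.37 in Huh-7D12 and -2.22 in SK-Hep-1 for 23 genes of the urea cycle and amino acid catabolism, and 0.61 in Hep3B, 1.60 in HepG2, -0.53 in Huh-7D12 and -1.10 in SK-Hep-1 for 27 genes of bile acid and lipid metabolism. ALDH1A1, an aldehyde dehydrogenase gene, was 934-fold (429 to 2547) lower in SK-Hep-1, as were the sulfotransferase genes SULT2A1 (at least 79.9-fold) and SULT1A1 (69.2-fold (26.8 to 255)). HGD, of tyrosine breakdown, had 0 reads in SK-Hep-1 and was at least 405-fold lower. FABP1, MTTP and LIPC, which act in lipid transport, were at least 1071-fold, 632-fold (246 to 2320.5) and 391-fold (69.7 to 15468) lower. In HepG2, the glucuronosyltransferase gene UGT2B10 was 43.3-fold (34.5 to 55.0) higher and HPD, of the same pathway as HGD, was 18.8-fold (16.4 to 21.5) higher. HAL, which encodes histidine ammonia-lyase, was 8.95-fold (7.99 to 10.1) higher in Hep3B. Without SK-Hep-1, the medians of the 3 lists were 1.43, 0.85 and 1.20 in HepG2 and -1.08, -0.77 and -1.01 in Huh-7D12, all outside the matched lists. In Hep3B those of the urea cycle and of bile acid metabolism turned to -0.08 and -0.14 and that of xenobiotic metabolism was 0.17, all within them. The bile acid median of Huh-7D12 lay within them with a pseudocount of 4 (-0.22), an entry level of 5 (-0.14) or none (-0.18).

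Mesenchymal and matrix genes stood at the opposite side in SK-Hep-1. Of 35 mesenchymal genes, 18 stood higher there and 1, TGFBI, stood lower (27.5-fold (23.2 to 32.8)). The medians were -1.07 in Hep3B, -0.88 in HepG2, -0.41 in Huh-7D12 and 3.46 in SK-Hep-1. CD44, a receptor for hyaluronan, reached 1426 and was 1199-fold (829.7 to 1805) higher, the receptor tyrosine kinase gene AXL was 73.3-fold (64.8 to 83.3) higher, and THY1, without reads in the other 3 lines, was at least 322-fold higher. VIM, the gene of the intermediate filament vimentin, was at 6046 in SK-Hep-1, 784 in Huh-7D12 and 274 in Hep3B, and had 2 reads in HepG2. Of 29 genes of collagens and matrix, 17 stood higher in SK-Hep-1, and the medians were -1.48 in Hep3B, -1.97 in HepG2, -0.95 in Huh-7D12 and 3.49 in SK-Hep-1. COL6A2 was 296-fold (185 to 509) higher, COL4A2 401-fold (194 to 999), COL13A1 at least 370.0-fold and the laminin gene LAMB3 175-fold (122 to 262). With SK-Hep-1 left out, the mesenchymal median turned positive in HepG2 (0.37) and in Huh-7D12 (0.26, within the matched lists), and that of the collagens in Huh-7D12 was 1.24.

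MME, IL1B and IL6 were among the genes with the largest distance in SK-Hep-1. MME (ENSG00000196549, chromosome 3, 155024124 to 155183729), the gene of the membrane peptidase neprilysin, was at 1716 and was 20212-fold (5595 to 166901) higher. The cytokine genes IL1B and IL6 were 10661-fold (2951 to 88042) and 3934-fold (1536 to 14442) higher, the proteoglycan gene SRGN 7861-fold (2689 to 38121), the secreted Wnt antagonist gene SFRP1 4808-fold (1645 to 23319.5) and the phosphodiesterase gene PDE1C 10968-fold (1968 to 433257). LINC02154, without reads in the other 3 lines, was at least 1902-fold higher. Markers of other liver cell types were measured for 12 endothelial, 9 stellate, 12 cholangiocyte and 5 leukocyte and Kupffer genes, where 32, 18, 20 and 26 were listed. The rest did not pass the entry level in any line or were not in the data. None of these lists lay outside the matched lists in SK-Hep-1 at the entry level of 1. Of 12 endothelial markers, 3 stood higher there (FLI1, 47.8-fold (31.6 to 76.0); ENG, 22.8-fold (15.6 to 34.9); ROBO4, 14.3-fold (9.19 to 23.4)), and PECAM1, which encodes an adhesion protein of endothelial cells, had 0 reads. EGFL7 was 18.3-fold (9.12 to 42.8) lower in HepG2. The endothelial medians were -0.81 in Hep3B, -0.03 in HepG2, 0.49 in Huh-7D12 and -0.10 in SK-Hep-1, the one in SK-Hep-1 at the 56.0th percentile of matched lists. The stellate cell medians were 0.43 in Hep3B, 0.77 in HepG2, -0.24 in Huh-7D12 and -0.45 in SK-Hep-1 over 9 measured genes, among which RELN (354-fold (163 to 967)) and BAMBI (5.78-fold (4.59 to 7.36)) stood lower and ECM1 higher (12.5-fold (8.10 to 20.3)) in SK-Hep-1. The cholangiocyte medians were -0.31 in Hep3B, 0.37 in HepG2, -0.05 in Huh-7D12 and -0.14 in SK-Hep-1, with KRT7 232-fold (79.1 to 1130.2) higher in SK-Hep-1 and SPP1 64.9-fold (29.5 to 178) lower in Hep3B. The leukocyte and Kupffer cell medians were 0.14 in Hep3B, 0.68 in HepG2, 0.16 in Huh-7D12 and -0.72 in SK-Hep-1 over 5 measured genes, with LYZ, the lysozyme gene, at 2364 in HepG2 and 1 read in SK-Hep-1 and TIMD4 76.4-fold (13.4 to 3051) higher in Huh-7D12. Of these 4 marker lists, the medians lay outside the matched lists for endothelial markers in Hep3B and for stellate markers in HepG2. The first call ended with an entry level of 5 (-1.68), and the second with that level (0.77), with a pseudocount of 0.25 (0.91), without SK-Hep-1 (0.43) and with no entry level, where the median was -0.09. Other calls were gained. With an entry level of 5, stellate (-1.80) and leukocyte and Kupffer markers (-7.58) lay outside in SK-Hep-1. In HepG2, leukocyte and Kupffer (7.27) and cholangiocyte markers (0.83) did so at that level. The leukocyte and Kupffer values at an entry level of 5 were those of LYZ alone and do not describe the list. Leukocyte and Kupffer markers also lay outside in HepG2 with a pseudocount of 0.25 (1.21). Cholangiocyte markers did in HepG2 with one of 4 (0.36) and in Huh-7D12 with no entry level (0.28).

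Cell cycle genes were lower and interferon genes higher in SK-Hep-1, and p53 target genes were higher in SK-Hep-1 and HepG2 than in Hep3B and Huh-7D12. Over 38 proliferation genes, 7 stood lower in SK-Hep-1 and the medians were 0.65 in Hep3B, 0.48 in HepG2, 0.84 in Huh-7D12 and -1.77 in SK-Hep-1. CCNA2, MYBL2, PLK1 and KIF20A, which act in the cell division cycle, were 9.28-fold (8.03 to 10.8), 7.43-fold (6.27 to 8.86), 5.72-fold (4.81 to 6.85) and 5.55-fold (4.82 to 6.41) lower. Without SK-Hep-1 the proliferation medians lay within the matched lists, at 0.04 in Hep3B, -0.22 in HepG2 and 0.21 in Huh-7D12. Of 36 interferon response genes, 9 stood higher in SK-Hep-1 and 4 lower in Huh-7D12, with medians of -1.09 in Hep3B, 0.24 in HepG2, -1.06 in Huh-7D12 and 2.11 in SK-Hep-1. IFIT2 and IFIT3 were 40.4-fold (25.6 to 67.7) and 12.5-fold (9.37 to 17.0) higher in SK-Hep-1, as was HLA-B (10.1-fold (9.13 to 11.3)), and the antiviral gene IFITM3 was 10.2-fold (9.13 to 11.5) lower in Huh-7D12. Of 33 p53 target genes, 2 stood higher in SK-Hep-1, and the medians were -1.03 in Hep3B, 0.71 in HepG2, -0.63 in Huh-7D12 and 1.19 in SK-Hep-1. SFN was 64.8-fold (27.3 to 202) lower in Hep3B, while TP53INP1 was 5.44-fold (4.86 to 6.11) higher there. PLK2 was 5.90-fold (5.68 to 6.13) higher in SK-Hep-1. Of 26 target genes of TGF-beta and YAP, 7 stood higher in SK-Hep-1 and 6 lower, with medians of -0.49 in Hep3B, 0.40 in HepG2, 0.16 in Huh-7D12 and 0.58 in SK-Hep-1: INHBA was 27.8-fold (22.5 to 34.6) higher and ID1, an inhibitor of bHLH factors, 142-fold (60.5 to 437) lower. Of 24 HOX genes, 6 stood higher in SK-Hep-1, and the medians were -0.95 in Hep3B, -1.11 in HepG2, -0.12 in Huh-7D12 and 1.29 in SK-Hep-1. Those with the largest distance lay in the HOXB cluster: HOXB9 was 1321-fold (237 to 52224) higher, HOXB7 38.1-fold (24.7 to 62.0), HOXB13 73.3-fold (28.3 to 271) and HOXB3 at least 56.6-fold. Without SK-Hep-1 the HOX median of Huh-7D12 rose to 1.44, outside the matched lists. With an entry level of 5 the HOX medians of Hep3B, HepG2 and SK-Hep-1 (-1.28, -1.33 and 1.90) lay within the matched lists, as did that of Hep3B without SK-Hep-1 (-0.64). So did those of TGF-beta and YAP targets in Hep3B with a pseudocount of 0.25 (-0.34) and in HepG2 with one of 4 (0.13) or without SK-Hep-1 (0.10).

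HepG2 had high levels of Wnt, NRF2 and glycolytic target genes. Of 22 target genes of Wnt and beta-catenin, 8 stood higher in HepG2, and the medians were -0.54 in Hep3B, 1.95 in HepG2, -0.42 in Huh-7D12 and -1.96 in SK-Hep-1. The transporter genes SLC13A3 and SLC1A2 were 1452-fold (260.1 to 57374) and 426-fold (145 to 2069) higher, and NOTUM and SP5, which feed back on the pathway, were 45.2-fold (38.6 to 53.3) and 38.6-fold (28.1 to 54.6) higher. Among 21 NRF2 target genes, 5 stood higher in HepG2, with medians of -1.14 in Hep3B, 0.74 in HepG2, -0.41 in Huh-7D12 and -0.09 in SK-Hep-1. The aldo-keto reductase genes AKR1C3, AKR1C2 and AKR1B10 were 199.9-fold (123 to 350.3), 114-fold (80.7 to 165) and 42.9-fold (32.0 to 58.9) higher. The 33 genes of hypoxia and glycolysis had medians of -1.16 in Hep3B, 1.03 in HepG2, -0.06 in Huh-7D12 and -0.00 in SK-Hep-1; the glucose transporter gene SLC2A3 was 11.5-fold (10.7 to 12.5) higher in HepG2, while PFKP and HK1 were 58.9-fold (47.5 to 73.8) and 45.7-fold (34.3 to 62.2) higher and ALDOC 54.1-fold (23.0 to 168) lower in SK-Hep-1. By distance alone, DHRS2 (ENSG00000100867, chromosome 14, 23630115 to 23645639), a short-chain dehydrogenase gene, came first in HepG2 at 2718, 1320.2-fold (1023 to 1734) higher. BPIFB2, CPLX2 and HEPACAM were 3132-fold (867 to 25875), 1538-fold (526 to 7462) and 2685-fold (481 to 106095) higher, and CES1, a carboxylesterase gene without reads in the other 3 lines, at least 447-fold. VIM (2509-fold (694 to 20723)), RND3 (348-fold (136 to 1279)), ATL3 (at least 364-fold) and GPD2 (at least 340.1-fold) stood lower. Without SK-Hep-1, the HepG2 medians were 1.58 for Wnt targets, 1.04 for NRF2 targets, 1.07 for glycolysis and 0.97 for interferon genes. The Wnt medians were then -1.48 in Hep3B and -1.33 in Huh-7D12, both outside the matched lists. The NRF2 median of Huh-7D12 lay within the matched lists with a pseudocount of 0.25 (-0.34) or without SK-Hep-1 (-0.37).

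In Hep3B, the imprinted noncoding RNA H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470) was at 5344, 4074-fold (2738 to 6358) higher. The oncofetal list to which it belongs had medians of 1.72 in Hep3B, 1.08 in HepG2, 0.05 in Huh-7D12 and -4.07 in SK-Hep-1 over 14 genes; that of HepG2 lay within the matched lists with no entry level (0.10) or without SK-Hep-1 (0.18). AFP, the gene of alpha-fetoprotein, was at 468 in Hep3B, 8491 in HepG2, 23994 in Huh-7D12 and 0.686 in SK-Hep-1, and GPC3 and TRIM71 had 0 reads in SK-Hep-1 and were at least 2282-fold and at least 723-fold lower. Of 23 genes of epithelial adhesion and keratins, 4 stood higher in Hep3B and 6 lower in SK-Hep-1, with medians of 1.70 in Hep3B, 0.25 in HepG2, 0.06 in Huh-7D12 and -1.81 in SK-Hep-1. ESRP1, an epithelial splicing regulator, was 586-fold (162 to 4841) higher in Hep3B, CLDN4 was 74.8-fold (39.1 to 165) higher in HepG2, and EPCAM and LSR were 45.3-fold (22.8 to 105) and 44.1-fold (28.1 to 73.6) lower in SK-Hep-1. The histone genes HIST1H4I and HIST1H3J were 877-fold (242 to 7242) and 66.4-fold (51.8 to 86.8) higher in Hep3B, S100A14 75.5-fold (53.4 to 110.5), FBN3 148-fold (57.7 to 545) and the zinc finger gene ZNF135 at least 202-fold. The metallothionein gene MT1E (133-fold (89.2 to 208)), MAP1B (121-fold (65.4 to 253)), the cytokine receptor gene OSMR (467-fold (129 to 3859)) and SLC25A24 (at least 256-fold) stood lower.

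In Huh-7D12, SPINK1 (ENSG00000164266, chromosome 5, 147824568 to 147831786), the gene of a secreted trypsin inhibitor, was at 837, 799-fold (559.6 to 1185) higher. BRDT, whose protein acts in male germ cells, DCAF4L2, LINC01419 and the histone gene HIST1H4L had no reads in the other 3 lines and were at least 526-fold, at least 668-fold, at least 720.0-fold and at least 510.3-fold higher. UCA1 was 183-fold (107 to 344) higher, LGSN 268-fold (123 to 731) and FABP3, a fatty acid binding protein gene, 135-fold (88.4 to 219). LGALS3BP (156-fold (104 to 247)), CD74 (130.1-fold (62.9 to 324)), MAGED1 (at least 559.5-fold) and CHM (at least 291-fold) stood lower. In the 3 lines without SK-Hep-1, the genes that stood higher and lower numbered 398 and 178 in Huh-7D12 and 210 and 132 in Hep3B, and 389 stood lower in HepG2.

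By their medians, ribosomal protein genes were higher in SK-Hep-1, where factors of circRNA formation and histone genes were lower, and mitochondrially encoded genes were higher in HepG2 and lower in Huh-7D12, all outside the matched lists. Over 44 factors of circRNA formation and turnover the medians were 0.19 in Hep3B, -0.02 in HepG2, 0.17 in Huh-7D12 and -0.39 in SK-Hep-1, of which that of Hep3B lay within the matched lists with no entry level (0.18) or without SK-Hep-1 (0.07). ESRP2 was 32.2-fold (14.6 to 88.6) lower and the muscle splicing factor gene RBM20 105-fold (28.5 to 876) higher in SK-Hep-1. The 14 measured replication-dependent histone genes and short RNAs had medians of 0.24 in Hep3B, -0.07 in HepG2, 0.46 in Huh-7D12 and -0.83 in SK-Hep-1. HIST1H2BK was 7.47-fold (6.83 to 8.17) lower in HepG2 and HIST1H1D 8.05-fold (6.20 to 10.6) higher in Huh-7D12. Mitochondrially encoded genes had medians of -0.23 in Hep3B, 1.15 in HepG2, -0.68 in Huh-7D12 and -0.11 in SK-Hep-1, and they took 29.2% of gene reads in Hep3B, 47.4% in HepG2, 17.4% in Huh-7D12 and 34.8% in SK-Hep-1. Most of these reads came from MT-RNR2, the large mitochondrial ribosomal RNA, at 25.6%, 41.5%, 13.8% and 29.5% in the same order. MT-CO1 was at 10119 in HepG2, 2.29-fold (2.27 to 2.31) above the nearest line. The 29 cytosolic ribosomal protein genes had medians of -0.69 in Hep3B, -0.13 in HepG2, -0.16 in Huh-7D12 and 1.03 in SK-Hep-1, with RPL10 3.09-fold (3.04 to 3.15) and RPS18 2.74-fold (2.70 to 2.79) above the nearest line in SK-Hep-1 and RPSA 3.53-fold (3.46 to 3.60) in Huh-7D12, none of them past 4-fold, and the median of Hep3B without SK-Hep-1 was -0.35, within the matched lists.

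The second comparison asked which circRNAs the lines expressed. Their most abundant circRNAs came from genes expressed in all 4 lines, such as NFATC3, CDYL, FNDC3B and HIPK3. The circRNA of exons 2 to 3 of NFATC3 (chromosome 16, 68121987 to 68126610, plus strand, coding sequence), a gene of a calcium-regulated transcription factor, had the highest mean, with 135 (115 to 159) in Hep3B, 304 (265 to 347) in HepG2, 166 (141 to 194) in Huh-7D12 and 53.8 (38.5 to 73.3) in SK-Hep-1. A second circRNA, of NFATC3 exon 2 alone (chromosome 16, 68121987 to 68123121), was at 51.6, 155, 54.2 and 14.8. The exon 2 circRNA of CDYL (chromosome 6, 4891713 to 4892379), whose protein acts on chromatin, was at 88.2, 65.5, 49.8 and 57.9 in the same order. That of HIPK3 exon 2 (chromosome 11, 33286413 to 33287511), which spans part of the 5' UTR and coding sequence of a kinase gene, was at 44.5, 15.3, 55.2 and 44.4. FGD6 exon 2 (chromosome 12, 95208843 to 95211267) reached 119.8 in SK-Hep-1, and CAMSAP1 exons 2 to 3 (chromosome 9, 135881633 to 135883078) 88.8 in Huh-7D12. FNDC3B exons 5 to 6 (chromosome 3, 172247533 to 172251541), ASPH exons 2 to 3 (chromosome 8, 61680968 to 61684188) and ZKSCAN1 exons 2 to 3 (chromosome 7, 100023419 to 100024307) were at 13.5, 10.8 and 18.8 in SK-Hep-1 and between 24.9 and 81.2 in the other 3 lines. A circRNA of ZNF124 (chromosome 1, 247156406 to 247159813) with 1 end at an annotated exon end was at 129 in Huh-7D12.

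**Figure D2:**
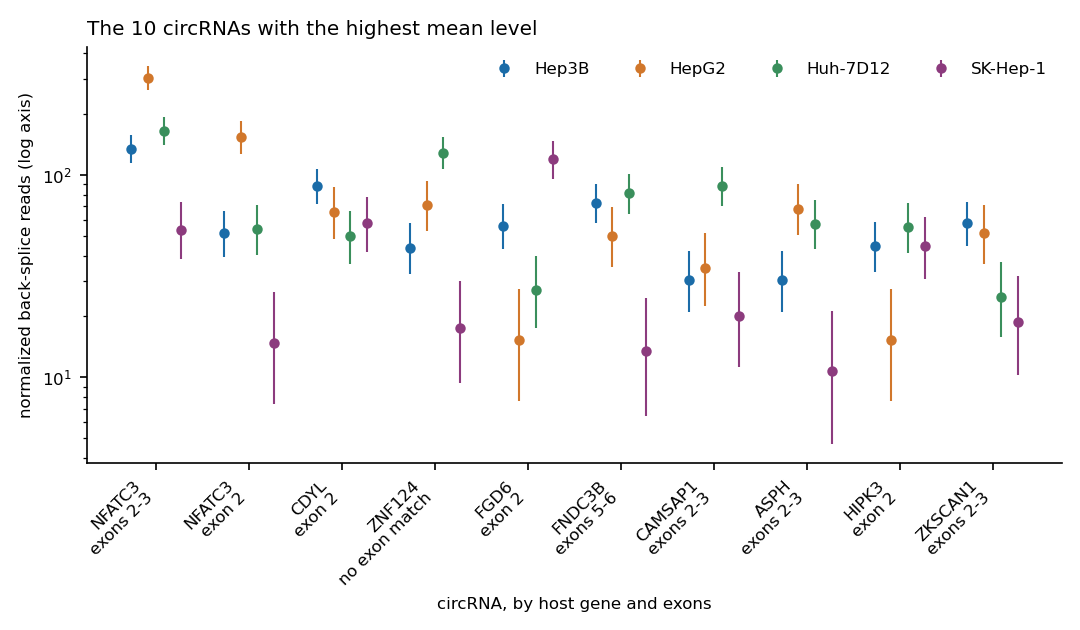
Level of the 10 circRNAs with the highest mean over the 4 lines, in normalized back-splice reads on a log axis, by host gene and exons. Each point is 1 library and each bar the 95% Poisson interval of its reads; the circRNA of NFATC3 exons 2 to 3 lies between 53.8 and 304.

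Of the 8000 circRNAs with a value in at least 1 line, 3966 were seen in Hep3B, 2383 in HepG2, 4089 in Huh-7D12 and 2742 in SK-Hep-1. They were seen in 1 line (4810), 2 lines (1783), 3 lines (824) or all 4 lines (583), and came from 3366 host genes. UBAP2 gave 27 circRNAs, SMARCC1 23, and PPP6R3 and PTK2 21 each. Both ends lay at annotated exon ends for 85.2%. Of those matched to a transcript, the median held 4 exons and 519 nt, and 32.0% began at exon 2. The 10 most abundant circRNAs of a line took 6.17% (95% Wilson interval 5.77 to 6.60) of its back-splice reads in Hep3B, 11.3% (10.5 to 12.1) in HepG2, 5.54% (5.17 to 5.94) in Huh-7D12 and 6.38% (5.86 to 6.95) in SK-Hep-1. On a per-million scale of gene reads outside mitochondrial genes, there were 747 back-splice reads in Hep3B (734 to 760.3), 516 in HepG2 (504 to 529), 881 in Huh-7D12 (866 to 896) and 567 in SK-Hep-1 (555 to 580.1). Detection depended on the reads required: with at least 5 times the circRNA pseudocount required, 323, 224, 414 and 325 circRNAs were seen in the same order and 59 in all 4 lines.

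CircRNAs that stood higher in 1 line were most frequent in SK-Hep-1. In SK-Hep-1 they came from genes such as ADAMTS6, LPAR1 and AXL, in Huh-7D12 from ALB and LPAR3, in HepG2 from CYP24A1, and in Hep3B from NECTIN3 and ESRP1. Of 777 circRNAs that entered, 62 stood higher and 28 lower in SK-Hep-1, 50 and 3 in Huh-7D12, 14 and 8 in HepG2, and 13 and 3 in Hep3B. With equal circRNA totals in the lines, 32 stood higher in HepG2 and 17 in Huh-7D12, which turned the order of these 2 lines, and with 4 times the circRNA pseudocount 12 stood higher in SK-Hep-1, 10 in Huh-7D12, 2 in HepG2 and 1 in Hep3B. In SK-Hep-1, exons 2 to 7 of ADAMTS6 (chromosome 5, 65451475 to 65473952), a metalloprotease gene, gave 81 reads and a level of 109, 78.2-fold (13.6 to 3126) above the nearest line. Exons 2 to 3 of LPAR1 (chromosome 9, 110972073 to 110973558), a lysophosphatidic acid receptor gene, were at 88.8, 82.0-fold (14.2 to 3288), and exons 2 to 4 (chromosome 9, 110941421 to 110973558) were at least 9.97-fold higher. The circRNAs of BABAM2 exons 5 to 7 (chromosome 2, 27987993 to 28045799) and AXL exons 5 to 6 (chromosome 19, 41230967 to 41231298) had 37 and 31 reads in SK-Hep-1, 0 in the other 3 lines, and were at least 11.9-fold and at least 9.97-fold higher. In Huh-7D12, a loop of exon 14 of ALB (chromosome 4, 73420254 to 73420321, 68 nt, coding sequence and 3' UTR) had 36 reads, LPAR3 exon 2 (chromosome 1, 84865385 to 84866138) 32, LINC01608 exons 1 to 5 (chromosome 8, 111003414 to 111027433) 28 and UNC13C exon 2 (chromosome 15, 54012648 to 54015886) 27, all with 0 in the other 3 lines, which put them at least 9.32-, 8.28-, 7.25- and 6.99-fold higher. In HepG2, exons 3 to 11 of CYP24A1 (chromosome 20, 54157169 to 54171670), which encodes the enzyme that inactivates vitamin D, were at 94.8, 21.3-fold (8.69 to 67.7) above the nearest line. DIP2C exons 7 to 9 (chromosome 10, 408926 to 415888) had 9 reads in HepG2, ITPR2 exons 27 to 37 (chromosome 12, 26550247 to 26602706) 7, and loops with no host gene assigned in the deposited table on chromosome 17 (7077982 to 7108557) and chromosome 16 (28595783 to 28608603) 11 and 7, all with 0 in the other 3 lines, which put them at least 3.11-, 2.42-, 3.80- and 2.42-fold higher. In Hep3B, a loop with no assigned host gene on chromosome 20 (56388156 to 56393031) had 23 reads, NECTIN3 exons 6 to 7 (chromosome 3, 111144899 to 111147484) 14, FAT3 exon 1 (chromosome 11, 92352096 to 92355404) 11, NF1 exons 16 to 20 (chromosome 17, 31223444 to 31227606) 10 and ESRP1 exons 7 to 9 (chromosome 8, 94664697 to 94665196) 9, with 0 in the other 3 lines, which put them at least 4.89-, 2.98-, 2.34-, 2.13- and 1.92-fold higher. The ALB loop is shorter than a 100-bp read, and errors of alignment were not tested for it. With 4 times the circRNA pseudocount, the circRNAs of NECTIN3, FAT3, NF1, ESRP1, DIP2C and ITPR2 and the chromosome 16 loop did not pass 4-fold. Few reads lay behind most of these: with 95% Poisson intervals that overlap no other line, a criterion chosen after seeing the data, 19 stood higher in SK-Hep-1, 17 in Huh-7D12, 5 in HepG2 and 3 in Hep3B. The numbers that stood lower in Hep3B, HepG2 and Huh-7D12 lay within those of simulated libraries without differences, and those of SK-Hep-1 above them (28 against at most 6), although 3 of SK-Hep-1 remained with Poisson intervals that do not overlap and 2 with 4 times the pseudocount.

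Among 66 genes named beforehand as hosts of well-studied circRNAs, 60 had a circRNA in these libraries when hosts were matched by gene symbol. The most abundant circRNA of a host stood higher in SK-Hep-1 for LPAR1, SLC8A1 and LINC00632, among others, and in Hep3B for FAT3. Examples that passed 4-fold in no line were FBXW7 exons 3 to 4 (chromosome 4, 152411303 to 152412529), between 19.5 and 47.2, MAN1A2 exons 2 to 5 (chromosome 1, 117402186 to 117420649), between 16.9 and 56.5, and XPO1 exons 3 to 5 (chromosome 2, 61522611 to 61533903), between 13.9 and 32.9. In SK-Hep-1, SLC8A1 exon 1 (chromosome 2, 40428473 to 40430304), from the gene of a sodium-calcium exchanger, had 29 reads against 0 in the other 3 lines. A circRNA within LINC00632 (chromosome X, 140783175 to 140784659), the transcript from which CDR1-AS is made, had 18 reads in SK-Hep-1 and 1 in Huh-7D12 (22.4-fold (3.53 to 932)). Under its own symbol CDR1-AS had no circRNA, but a circRNA assigned to LINC00632 can be CDR1-AS, so it cannot be called absent. GLIS3 exon 2 (chromosome 9, 4286038 to 4286523) was at 49.8 in Huh-7D12 and 12.5 in Hep3B, with 0 reads in HepG2 and 1 in SK-Hep-1. Exon 4 of SPECC1 (chromosome 17, 20204333 to 20205912), a position shared with AC004702.1, was at 93.5 in Hep3B, 37.9 in Huh-7D12, 5.58 in HepG2 and 1.35 in SK-Hep-1.

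The third comparison asked whether differences between lines in circRNA level went with those of the host gene. Circular and gene levels moved together in part: LPAR1, AXL and ADAMTS6 were high in SK-Hep-1 on both counts, and CYP24A1 in HepG2. Over 949 host genes, the Spearman correlation between the log2 difference of summed circRNAs and that of gene reads was 0.527 in Hep3B, 0.440 in HepG2, 0.539 in Huh-7D12 and 0.597 in SK-Hep-1. In Hep3B 59 host genes had differences at least 2 (log2) apart, in HepG2 118, in Huh-7D12 105 and in SK-Hep-1 134. The circular difference was the higher one for 30, 22, 84 and 63 in the same order, and the lower one for 29, 96, 21 and 71. The sides thus went with the few back-splice reads of HepG2 and the many of Huh-7D12, and equal circRNA totals left 67 in Huh-7D12. Of all host genes so counted, 5, 11, 6 and 17 in the same order had 0 back-splice reads and a gene level under 1 in that line. Among them were ALB in SK-Hep-1 and MYO10 and ABR in Huh-7D12. For these, both were low and the distance between them was set by the pseudocount. ALB was the extreme case in Hep3B and HepG2: its gene level was 10412 in Hep3B and 4910.0 in HepG2 with 0 back-splice reads, and 3011 in Huh-7D12 with 40. FGL1, at a gene level of 203, gave no back-splice reads in Hep3B, and VCAN, at 296 in Huh-7D12, gave 7 there. In HepG2, ANKRD11 and STAU1 had 0 back-splice reads at gene levels of 85.1 and 265, and PRCC had 7 at 33.7 against 0 in the other 3 lines. In Huh-7D12, SUMF1 had 26 at 15.6, ZNF91 had 0 at 60.5 and ZNF215 0 at 12.1. Few reads lay behind such zeros: ZNF91 had 8, 10 and 6 in Hep3B, HepG2 and SK-Hep-1, and ZNF215 had 5 in SK-Hep-1 only. Whether counting error alone could give such differences between circular and gene reads was not tested. In SK-Hep-1, LPAR3 had 0 back-splice reads at 37.7, against 32 at 17.0 in Huh-7D12, and PDE1C had 10 at 466.

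**Figure D3:**
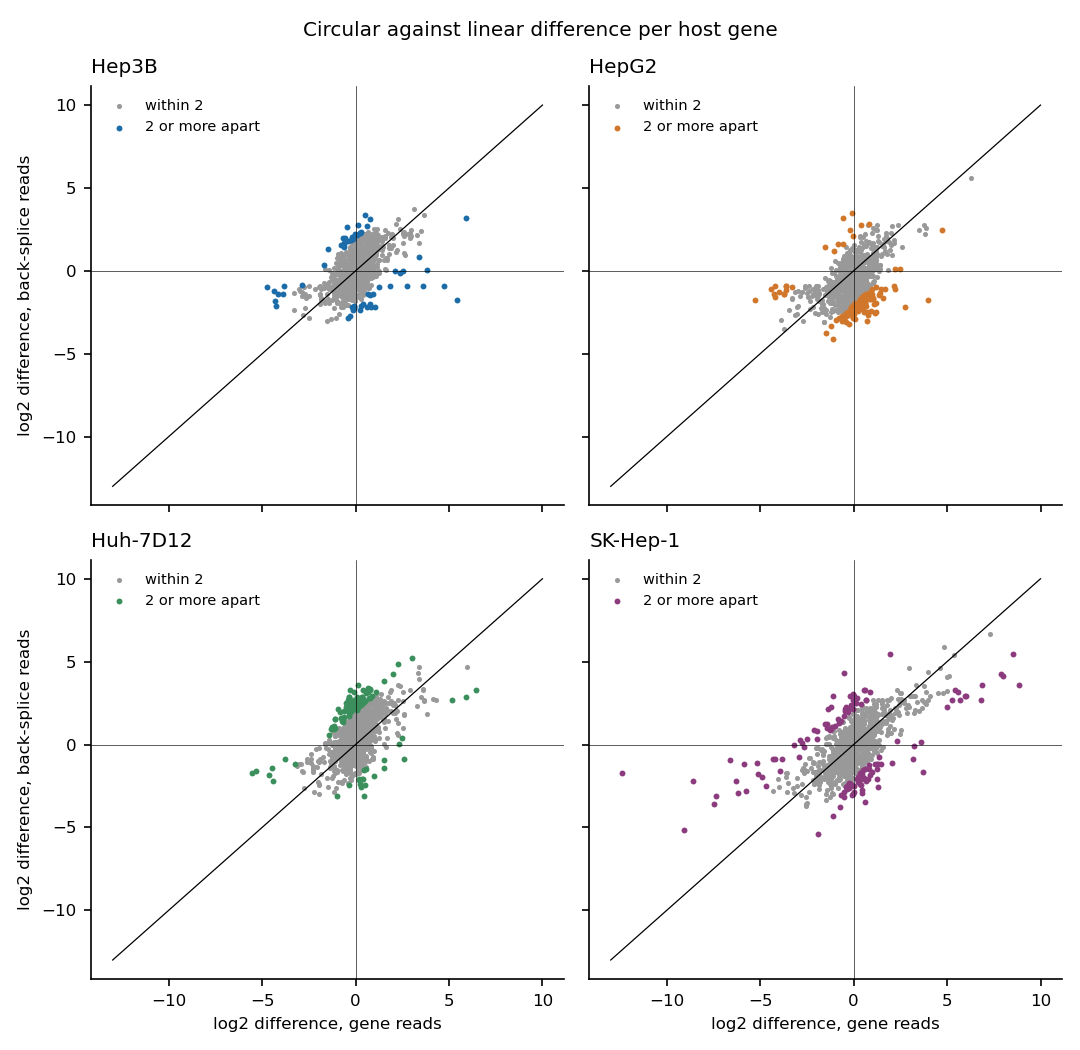
Log2 difference of each line to the mean of the other 3 lines for 949 host genes, in gene reads (horizontal axis) and in summed back-splice reads (vertical axis). Points in colour differ by at least 2 between the axes, the diagonal marks equal differences, and the number of such genes ranges from 59 in Hep3B to 134 in SK-Hep-1.

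Among hosts with a back-splice read and a gene level of at least 1 in the line, which were 799 in Hep3B, 692 in HepG2, 840 in Huh-7D12 and 732 in SK-Hep-1 and thus not the same genes in each, the median per 1000 gene reads was 5.04 back-splice reads in Hep3B (95% bootstrap interval over genes 4.51 to 5.61), 3.81 in HepG2 (3.37 to 4.23), 6.20 in Huh-7D12 (5.62 to 6.92) and 5.05 in SK-Hep-1 (4.51 to 5.68). SUMF1 reached 70.7 in Huh-7D12, where LPAR3 was at 79.8, and ALB was at 0.564. With a circRNA entry level of 10 pseudocounts the medians were 7.46 in Hep3B, 5.66 in HepG2, 10.2 in Huh-7D12 and 6.14 in SK-Hep-1. The counts of host genes with differences at least 2 apart depended on the pseudocounts, from 19, 23, 12 and 53 (Hep3B, HepG2, Huh-7D12, SK-Hep-1) with 4 times both to 164, 234, 247 and 248 with 0.25 times both.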

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

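The alternatives chosen after the results were seen were Poisson intervals that do not overlap, circRNAs with both ends at exon ends and 1 host, thinning of back-splice reads by the ratio that makes reads outside mitochondrial genes equal, and SK-Hep-1 left out. TMM scaling, median-of-ratios scaling and both other entry levels for genes kept all counts of genes within 1.5 times. Having no entry level could not change these counts, since a 4-fold distance with a pseudocount of 1 needs a level above 1. Median-of-ratios factors lay within 0.03 log2 of the deposited scaling, so that this setting could change little. TMM and median-of-ratios scaling kept the calls and signs of all 104 list medians. Thinning and the restriction to exon ends kept all circRNA counts they apply to. Values below are in the order Hep3B, HepG2, Huh-7D12, SK-Hep-1 unless lines are named. A pseudocount of 0.25, which spreads low levels apart by construction, gave 233, 360 and 439 genes higher in the first 3 lines and 139, 357, 147 and 801 lower, and one of 4 gave 48, 135, 91 and 498 higher and 18, 63, 26 and 255 lower. For single genes, the pseudocount of 4 took 10 under 4-fold. SK-Hep-1 left out, which removes 1 line that a gene must exceed, gave 210 genes higher and 132 lower in Hep3B, 389 lower in HepG2 and 398 higher and 178 lower in Huh-7D12, and 12 lists outside the matched lists in Hep3B. It reversed the medians of secreted proteins (-0.62), coagulation and complement (-1.11), mesenchymal genes (0.26) and collagens (1.24) in Huh-7D12, of hepatic transcription factors (-0.39), mesenchymal genes (0.37) and proliferation (-0.22) in HepG2, and of the urea cycle (-0.0753) and bile acid metabolism (-0.14) in Hep3B. Of these, mesenchymal genes in Huh-7D12, proliferation in HepG2 and both lists in Hep3B lay within the matched lists. A further 14 list medians lost their call and 8 gained one. Those gained were interferon genes in HepG2 (0.97) and, in Huh-7D12, oncofetal (-0.73), xenobiotic (-1.08), urea cycle (-0.77), epithelial (-0.73), Wnt (-1.33), TGF-beta and YAP (0.54) and HOX genes (1.44). Beside calls gained by liver cell markers, planned settings gave calls in Huh-7D12 to xenobiotic metabolism (-0.29) and Wnt targets (-0.37) with a pseudocount of 4, to oncofetal genes (0.72) and histones (0.46) with an entry level of 5, and to Wnt targets (-0.38) and histones (0.45) with none, which also gave one to interferon genes in HepG2 (0.21). With no entry level the stellate median in HepG2 reversed to -0.0907, and the cause was not tested. Over genes at the entry level in all 4 lines the correlations were 0.857 (Hep3B and HepG2), 0.724 (Hep3B and SK-Hep-1), 0.843 (HepG2 and Huh-7D12), 0.756 (HepG2 and SK-Hep-1) and 0.747 (Huh-7D12 and SK-Hep-1), and the cause was not tested. Few reads limit the circRNA results: 46.5% of the circRNAs of HepG2 and 23.9% of those of Huh-7D12 rested on 1 read. At least 2 times the pseudocount left 1307, 1274 and 1533 circRNAs detected in the first 3 lines and 208 in all 4, and 5 times left 323, 224, 414 and 325, and 59 in all 4. A circRNA pseudocount of 0.25 times the main one gave 22, 69, 23 and 73 circRNAs lower, and 4 times gave 1, 2, 10 and 12 higher and 0, 0, 1 and 2 lower, when 7 of the named circRNAs fell under 4-fold. No circRNA entry level gave 41, 58, 191 and 273 higher, and an entry level of 10 pseudocounts gave 3, 5, 18 and 21 higher, 1 lower in Hep3B and 17 lower in SK-Hep-1. Poisson intervals that do not overlap left 3, 5, 17 and 19 higher and 0, 0, 1 and 3 lower. Equal circRNA totals gave 32 higher in HepG2, 17 higher and 5 lower in Huh-7D12 and 1 lower in Hep3B, a correlation of circular with gene differences of 0.490 in HepG2 and 67 host genes at least 2 apart in Huh-7D12; this setting raises HepG2 and lowers Huh-7D12 by construction. Host genes at least 2 apart numbered 19, 23, 12 and 53 with 4 times both pseudocounts, 164, 234, 247 and 248 with 0.25 times both, 15, 40, 33 and 43 with the entry level of 10 pseudocounts, and 39, 52, 67 and 76 with the most abundant circRNA of a host alone. The higher entry level gave correlations of 0.698, 0.533, 0.648 and 0.693 and medians of 7.46, 5.66, 10.2 and 6.14 back-splice reads per 1000 gene reads, and the most abundant circRNA alone gave 4.28 in Hep3B and 4.35 in SK-Hep-1; the cause was not tested. Among circRNAs seen in at least 2 lines, the 10 most abundant took 8.22%, 13.5%, 7.96% and 9.04%, since fewer circRNAs share the total.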

Other observations

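The tests of host gene levels split by line and of mitochondrial reads, the segments tested for DNA loss, and the limit used to read the chromosome 19 test were chosen after the results were seen. Blocks of neighbouring genes had no reads in 1 line while every other line expressed them. In SK-Hep-1 these included MTAP, CDKN2A and CDKN2B on chromosome 9 (21802543 to 22009363), of which the latter 2 encode inhibitors of the cell cycle; 8 genes on chromosome 13 (19633681 to 20903048) from MPHOSPH8 through PSPC1, ZMYM2, CRYL1 and IFT88 to XPO4; and 21 genes on chromosome 19 (52397849 to 53496255), mainly of zinc finger proteins, from ZNF528 to ZNF813. The chromosome 13 genes had 18265 reads in the other 3 lines together, the chromosome 19 genes 20947 and the chromosome 9 genes 9518. Inside the chromosome 13 block, 10 circRNAs with 41 back-splice reads in the other lines had 0 in SK-Hep-1. The next expressed genes had reads in SK-Hep-1: LATS2 393 after the chromosome 13 block, and KLHL9 837 and CAAP1 173 around the chromosome 9 block. Clusters of liver genes were also silent in SK-Hep-1: FGB, FGA and FGG, which encode fibrinogen, on chromosome 4, the complement genes C8A and C8B with FYB2 on chromosome 1, and SERPINA11, SERPINA4 and SERPINA5 on chromosome 14, where SERPINA9 between them had 379 reads.

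Other lines had such blocks too. In HepG2, the zinc finger genes ZNF595, ZNF718 and ZNF141 at the start of chromosome 4 (53285 to 384864) had no reads, although 10 reads fell in other genes between them. In Huh-7D12, SNHG14, PWAR5, AC124312.5 and SNORD116-18, of an imprinted region on chromosome 15 (24978583 to 25419462), had none, against 9553 in the other 3 lines, while UBE3A beside them had 2276; other genes of that block kept 8 reads and its circRNAs 3. Of 319 X-linked genes expressed in the other 3 lines, 25 (7.84%, 95% Wilson interval 5.36 to 11.3) had no reads in Huh-7D12, against 20 of 10052 autosomal genes (0.199%, 0.129 to 0.307). APOOL, ZNF711 and CHM (X chromosome, 85003826 to 86047562) were neighbours among them, as were SPIN4, AMER1 and ZC4H2 (63347228 to 65034713) and SPIN3, SPIN2B and ZXDB (56818298 to 57597545). On fewer genes, the X-linked share also lay above the autosomal one in HepG2 (9 genes, 3.01% against 1.10%) and Hep3B (3 genes, 1.01% against 0.219%), with intervals that did not overlap. In SK-Hep-1 they overlapped (2.71% against 2.59%).

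The blocks of genes without reads were weighed first. Over the 4 lines there were 14 runs of 3 or more such neighbours, against at most 2 in 100 shuffles of the gene order, which argues against chance placement. Loss of the DNA segment requires that no gene inside has reads: the number of genes inside with more than 3 reads in SK-Hep-1 was 0 on chromosome 13, where 15 further genes had 330 reads in the other lines, and 0 on chromosome 9, where 3 further genes had 74. It was 1 on chromosome 19, the pseudogene NDUFV2P1 with 4 reads, and by the rule written beforehand this counts against a loss; after the value was seen it was read as undecided, because 4 reads do not exceed the limit of 3 by more than counting error. The chromosome 13 and 9 blocks may thus reflect lost DNA in SK-Hep-1, but silencing of a whole block would leave the same reads, and no DNA was analysed here.

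The circRNAs that stood higher in 1 line numbered 139, against at most 4 in 100 simulated sets of libraries with 1 common level per circRNA, which argues against counting error as the whole cause. Over the 4 lines, 130 of them had 1 host gene with gene reads to compare. For 46.2% of these circRNAs (95% exact interval 37.4 to 55.1, 60 of 130) the host stood at least 2-fold above every other line too. No such share was computed for the other circRNAs, and this one does not decide whether the host level accounts for them. A host with several such circRNAs, as LPAR1 in SK-Hep-1, counts more than once. The intervals treat these circRNAs as independent and are to that extent too narrow. Split by line, the share was 73.3% in SK-Hep-1 (60.3 to 83.9, 44 of 60), where the level of the host gene is a candidate explanation, and 22.9% in the other 3 lines together (13.7 to 34.4, 16 of 70); this argues against the host level as the main cause in Huh-7D12 (17.4%, 7.82 to 31.4, 8 of 46), while Hep3B (3 of 12, 5.49% to 57.2%) and HepG2 (5 of 12, 15.2% to 72.3%) alone do not exclude 50%. Both ends lay at annotated exon ends for 87.8% of these circRNAs (81.3 to 92.2), a lower share than the 93.7% of the others that entered (91.6 to 95.4), with intervals that overlap. This argues against mapping outside exons only for those with both ends there, and leaves it open for the rest. A majority was likely in any case, since most of the others also had both ends there. Intervals that overlap do not show that both shares are equal. Errors of alignment between annotated exon ends were not tested. The total of back-splice reads of each library also bears on these counts. With equal circRNA totals, 17 circRNAs stood higher in Huh-7D12 against 50 without, and 32 in HepG2 against 14. In Huh-7D12 a high total is thus a candidate explanation for part of the count, although this setting lowers Huh-7D12 by construction. Whether that total comes from the cells or from the library was not tested. Differences between the lines in circRNA formation or stability were not tested and stay open.

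HepG2 had the fewest back-splice reads. On a per-million scale of all gene reads it had 272, and the nearest line, SK-Hep-1, had 370. Outside mitochondrial genes HepG2 had 516 (504 to 529) and SK-Hep-1 567 (555 to 580.1). In these libraries the high mitochondrial share of HepG2 thus accounts for part of the gap, and what remains exceeds counting error. With the 50 most abundant nuclear genes also left out there were 621 (605 to 636), against 660.5 (646 to 675) in SK-Hep-1, so that a gap beyond counting error remained. The intervals do not cover the spread between libraries of a line, so neither result decides for the lines whether mitochondrial reads or abundant genes are the whole cause. RNA integrity, library preparation and a lower circRNA content of HepG2 cells were not tested and stay open, since each line has 1 library.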
